A study of Mus musculus with 24 samples.

How the data were processed

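Strand-specific RNA-seq libraries had been made with a SureSelect kit from total RNA of freshly isolated splenic B cells, purified on RNeasy micro columns, as the labels give it. The submitters' processing notes list Bowtie2 2.1.0, TopHat2 2.0.8, Cufflinks 2.1.1 and the genome build mm9. The authors deposited FPKM values, fragments scaled by transcript length and by the mapped fragments of the library, in 1 column per library, and neither the labels nor the file headers state the annotation, the treatment of reads that map to several genes or any filter. The reference annotation at hand is of another build, so no coordinates are given. Gene symbols are as in the tables, in which 25 names had taken the form of dates, such as 3-Mar, and could not be read as genes.

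Of 24 samples in 4 sorted populations, 12 were used. One table held the 6 CD93-negative libraries. The other was expected to hold 3 populations, and the columns used from it were the 6 CD93-positive libraries, while 6 further columns of values repeated them cell for cell and were not used. The remaining 12 samples, CD93-negative cells sorted as CD23-positive CD21-intermediate or CD23-negative CD21-low, were not analysed here. Comparisons planned for them were not run, namely the effect of the deficiency in those populations, differences of the effect between populations, comparisons of control populations and the signature drawn from them. The CD93-positive comparison had been planned as a fit over the libraries of all 3 populations and was fitted on 6, which is a departure from the plan. Groups were taken from the sample titles and genotype labels.

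FPKM holds no counts, so count models were not used. Because fragments are assigned fractionally and lengths enter the unit, counts could not be recovered and the depth of each library is unknown. The most frequent nonzero value among chemoreceptor genes, a rough reading of the worth of 1 fragment, lay between 0.138 and 0.265 FPKM in CD93-negative and between 0.0623 and 0.204 FPKM in CD93-positive libraries, smaller where a library is deeper. No interval or detection floor is given for that reason. Libraries of a group were compared before averaging. Pearson's r across tested genes, on log2 values, was 0.934 to 0.976 within groups. Between groups it was 0.919 to 0.943 in CD93-negative and 0.917 to 0.950 in CD93-positive libraries. The latter range overlaps the values within groups, as DKO replicate 3 had 0.934 and 0.940 with DKO replicates 1 and 2.

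Genes with at least 1 FPKM in at least 3 libraries of a table were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) on log2(FPKM + 1), without covariates, two-sided, within each table only because the tables were scaled separately. P-values were adjusted by Benjamini and Hochberg, with a threshold of 0.05. In the CD93-positive table, the fit with the authors' scaling gave every gene of a given expression level nearly the same spread, which makes its p-values depend on the size of a change more than on its own replicates. In a test on simulated values drawn from the real means and spreads, with 200 changed genes, the CD93-negative fit over 10960 genes recovered 88% of changes of 1 log2 unit and 97% of changes of 2, with 9 false calls among 194. The CD93-positive fit over 11250 genes recovered 3% and 78%, with 6 false calls among 87. That comparison can therefore show few changes of 1 log2 unit with the authors' scaling. Values were drawn independently for each gene, and the changed genes had a mean log2 value above 2. The false calls therefore do not measure errors from a shift shared by all genes of a library.

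Before the data were examined, 29 gene lists and 9 lists of cell type markers were fixed. Some share members, so their results are not independent. Xbp1, Edem1, Hsp90b1 and Pdia4, for example, are in both the plasma cell and the unfolded protein response list. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and also with an estimated correlation and with fry, which asks whether a list moves on balance in 1 direction and does not compare it with other genes. No gene of the list of immunoglobulin constant genes was in either table under the names used. Genes were named by a rule fixed at the same time. It took Tet1, Tet2, Tet3, Cd93, Fcer2a, Cr2 and Cd86, the 10 largest called increases and decreases with a mean of at least 5 FPKM in a group and no overlap of the groups, leaving out predicted, clone, small RNA and antigen receptor segment names, and up to 4 called members with the largest change of each list. Some genes that met the rule are not reported here.

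The alternatives were pseudocounts of 0.1 and 5, no filter and a filter of 5 FPKM, rescaling to a common upper quartile of the tested genes, quantile normalization, no trend, sample quality weights, the replicate number as a block, and each library left out. Added after the data were seen were a sex covariate, upper quartile rescaling without CD93-positive DKO replicate 3, subtraction of the mean chemoreceptor value followed by rescaling, scaling to a common sum without globins, and leaving out small RNA genes. CD93-positive control replicates 1 and 2 were male-like and the other CD93-positive libraries female-like. The sex covariate therefore sets the DKO libraries against control replicate 3 alone.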

Results

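RNA-seq gene expression values were examined for splenic B cells of C57BL/6 mice, sorted by surface markers from control animals (CTL) and from animals labelled as deficient in Tet2 and Tet3 (DKO). Tet2 and Tet3 encode dioxygenases that oxidise 5-methylcytosine in DNA. The labels listed 24 samples in 8 groups, and 12 libraries in 4 groups of 3 were used: control and DKO-labelled CD93-negative B cells, and control and DKO-labelled CD93-positive B cells. CD93 is a surface protein of immature, transitional B cells, though not of these alone. The other 12 samples, CD93-negative cells sorted further by CD23 and CD21, were not analysed here. Both tables held FPKM values for 23234 genes. The sum of FPKM ran from 342368 to 463987 over the CD93-negative libraries, with the 3 DKO-labelled libraries, 424032 or more, above the 3 control libraries, 394709 or less. FPKM values hold no counts, so the depth of each library is unknown. Among the CD93-positive libraries, DKO replicate 3 had a sum of 309359, against 523898 to 597968 in the other 5. Values below are mean ± SD with n = 3 libraries per group. Log2 changes are DKO minus control on the log2(FPKM + 1) scale, which understates changes of low genes. Adjusted p-values are from limma with Benjamini-Hochberg adjustment. The labels did not state that replicates were separate animals, so p-values measure only the spread between these libraries. In CD93-positive cells with the authors' scaling that spread was nearly the same for all genes of like expression. Very small p-values there do not reflect the replicates of a single gene.

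The targeted genes were read first, as a check of the labels. In CD93-negative cells Tet2 was at 6.36, 8.11 and 8.79 FPKM in the 3 control libraries and at 9.94, 8.15 and 9.40 FPKM in the 3 DKO-labelled libraries (log2 change 0.22, adjusted p = 0.336). Tet3 was at 14.8, 20.1 and 19.0 FPKM in control and at 15.7, 15.6 and 14.9 FPKM in DKO-labelled libraries (log2 change -0.20, adjusted p = 0.360). After rescaling each library to a common upper quartile its log2 change was -0.41, which passed the threshold of 0.05 (adjusted p = 0.00180, with 0.00180 to 0.634 over its alternatives). In CD93-positive cells Tet2 was at 3.18, 3.47 and 3.10 FPKM against 3.55, 2.29 and 1.80 FPKM (adjusted p = 0.731), and Tet3 at 12.1, 13.01 and 14.1 FPKM against 9.92, 7.67 and 3.84 FPKM (adjusted p = 0.222). After rescaling the Tet3 change in CD93-positive cells was -0.66 and passed (adjusted p = 0.0150). It passed without DKO replicate 3 (adjusted p = 0.0350), and not with sex as a covariate (log2 change -0.67, adjusted p = 0.101, with 0.00811 to 0.948 over its alternatives). Tet1 stayed at or under 1.025 FPKM in all 12 libraries and was not tested. A value per gene includes exons outside a deleted part, which the labels do not give, so these values check neither label, and the libraries are called DKO-labelled for that reason.

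The first comparison asked how the combined deficiency changed gene expression in CD93-negative B cells. Cd86, which encodes a costimulatory ligand for T cells, rose from 8.29 ± 0.623 to 17.8 ± 0.763 FPKM (log2 change 1.01, SE 0.13, adjusted p = 1.19e-04). Igj, the joining chain of polymeric antibodies, rose from 7.79 ± 2.88 to 208 ± 14.5 FPKM, a 26.8-fold difference of the means. Cr2 and Fcer2a, which encode the sort markers CD21 and CD23, fell from 104 ± 11.8 to 43.0 ± 0.680 FPKM and from 341 ± 35.9 to 167 ± 0.984 FPKM. Cd93 was at 4.34 ± 0.408 against 3.62 ± 0.272 FPKM (log2 change -0.21, adjusted p = 0.330), and its change of -0.39 after upper quartile rescaling passed (adjusted p = 0.0140, with 0.0140 to 0.672 over its alternatives).

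Of 10960 genes tested, 2351 passed an adjusted p of 0.05, 2045 higher and 306 lower in DKO-labelled libraries. This split depended on scaling. With the authors' scaling the median log2 change over all tested genes was 0.11, and after rescaling each library to a common upper quartile it was -0.08, with 1869 genes higher and 2609 lower. Of the 2351 genes, 2090 were called in the same direction after rescaling and 0 in the opposite one. Changes of gene lists are given relative to the median of all tested genes for that reason. Without control replicate 1, whose tested genes had the lowest upper quartile, 18.7 FPKM against 23.0 to 26.1 in the others, 2132 genes were higher and 1121 lower. Without DKO replicate 3 the counts were 1249 and 181.

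Of the 10 largest increases in named genes, 4 were in interferon-inducible GTPases: Iigp1, Tgtp1, Tgtp2 and Gbp10. Iigp1 rose from 0.353 ± 0.0939 to 42.5 ± 2.36 FPKM (log2 change 5.01, SE 0.13, adjusted p = 5.25e-10). Tgtp1 and Tgtp2 rose by 3.89 and 3.51 on the log2 scale and Gbp10 by 3.30, but these have near-identical relatives between which reads could be split, so each value is uncertain. Socs1, an inhibitor of cytokine signalling, rose from 4.09 ± 0.285 to 49.3 ± 5.74 FPKM. Serpina3f, a serine protease inhibitor, rose by 3.75 and Fam46c by 3.51. Prg2 was listed at 0 in all 3 control libraries and at 10.2, 11.5 and 14.7 FPKM in the DKO-labelled libraries. Of 25 tested interferon-stimulated genes, 24 rose and 0 fell, with the same counts adjusted over the list alone (median log2 change 0.91 relative to all tested genes, camera adjusted p = 4.59e-15, or 0.484 with an estimated correlation). Among them Zbp1, a nucleic acid sensor, was at 19.2 ± 0.335 against 82.4 ± 0.363 FPKM, and Isg20 at 5.94 ± 1.09 against 20.8 ± 2.02 FPKM.

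Of 25 tested proliferation genes, 23 rose and 0 fell, or 24 and 0 adjusted over the list alone (median log2 change 1.34 relative to all tested genes, camera adjusted p = 1.27e-18, or 0.484 with an estimated correlation). Mki67, a nuclear protein of cycling cells, was at 6.26 ± 1.60 against 33.8 ± 1.76 FPKM, Ccnb2, a mitotic cyclin, at 2.51 ± 0.423 against 17.8 ± 2.92 FPKM, and Rrm2, a subunit of ribonucleotide reductase, at 5.63 ± 2.07 against 32.2 ± 0.684 FPKM. Of 17 tested plasma cell genes, 14 rose and 0 fell, with the same counts adjusted over the list alone (median log2 change 0.78 relative to all tested genes, camera adjusted p = 6.60e-07, or 0.723 with an estimated correlation). Besides Igj, these included Prdm1, a transcription factor of plasma cell differentiation, at 0.632 ± 0.211 against 3.19 ± 0.157 FPKM, and the endoplasmic reticulum chaperone gene Hsp90b1 at 141 ± 23.7 against 366 ± 19.9 FPKM. In the list of the unfolded protein response 12 of 15 tested genes rose, also adjusted over the list alone (median log2 change 0.68 relative to all tested genes, camera adjusted p = 4.64e-06, or 0.749 with an estimated correlation). Xbp1, its transcription factor, was at 35.8 ± 5.92 against 84.5 ± 4.17 FPKM. Of 15 tested glycolysis genes 11 rose and 1 fell, or 12 and 1 adjusted over the list alone (median log2 change 0.59 relative to all tested genes, camera adjusted p = 1.99e-04, or 0.795 with an estimated correlation), with Gapdh at 164 ± 20.7 against 406 ± 14.97 FPKM. Heat shock genes, which can also mark stress during cell isolation, rose in 6 of 8 tested members, or 8 adjusted over the list alone (median log2 change 0.48 relative to all tested genes, camera adjusted p = 0.00361, or 0.795 with an estimated correlation). Genes higher and lower after upper quartile rescaling numbered 23 and 0 in the proliferation list, 14 and 1 in the plasma cell list and 12 and 0 in that of the unfolded protein response. For glycolysis they numbered 11 and 1, and for heat shock 6 and 0. The camera adjusted p then ran from 6.01e-17 to 4.99e-04 over these 5 lists, and with an estimated correlation from 0.0694 to 0.146.

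Genes used to tell B cell subsets apart moved in both directions. Of 15 tested genes of age-associated B cells 9 rose and 0 fell, or 11 and 0 adjusted over the list alone (median log2 change 0.83 relative to all tested genes, camera adjusted p = 6.60e-07, or 0.534 with an estimated correlation). Itgam, an integrin subunit also found on myeloid and B-1 cells, was at 1.24 ± 0.459 against 16.5 ± 1.13 FPKM, and Cxcr3, a chemokine receptor, at 4.45 ± 1.33 against 28.0 ± 1.59 FPKM. In the list of B-1 cell genes 8 of 13 rose and 1 fell, or 9 and 2 adjusted over the list alone (median log2 change 0.76 relative to all tested genes, camera adjusted p = 0.00150, or 0.749 with an estimated correlation). In that of germinal center genes 7 of 13 rose and 1 fell, or 8 and 1 adjusted over the list alone (median log2 change 0.89 relative to all tested genes, camera adjusted p = 1.90e-04, or 0.484 with an estimated correlation). Mef2b, a transcription factor, was at 3.05 ± 0.340 against 16.9 ± 1.0305 FPKM. Of 15 tested marginal zone B cell genes 8 fell and 2 rose, or 11 and 3 adjusted over the list alone (median log2 change -0.57 relative to all tested genes, camera adjusted p = 3.85e-07, or 0.526 with an estimated correlation). S1pr3, a sphingosine phosphate receptor, was at 6.38 ± 0.357 against 1.58 ± 0.252 FPKM, and Dtx1, a Notch target, at 41.8 ± 6.04 against 18.1 ± 1.08 FPKM. Of 7 tested transitional B cell genes 2 fell (median log2 change -0.26 relative to all tested genes, camera adjusted p = 0.0293, or 0.804 with an estimated correlation), with the same count adjusted over the list alone. Of 10 pan-B cell markers 2 fell (median log2 change -0.24 relative to all tested genes, camera adjusted p = 0.0124, or 0.855 with an estimated correlation, 0 higher and 2 lower adjusted over the list alone), Fcer2a among them. Genes higher and lower after upper quartile rescaling numbered 9 and 1 in the age-associated list, 8 and 3 in the B-1 list and 7 and 3 in the germinal center list. They numbered 1 and 11 in the marginal zone list, 0 and 5 in the transitional list and 0 and 7 in the pan-B list. Camera then called 5 of these 6 lists, and the transitional list had an adjusted p of 0.0501. The adjusted p of the 6 with an estimated correlation was 0.129 to 0.364.

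The largest decreases were in Slfn1, at 16.8 ± 1.27 against 1.12 ± 0.155 FPKM, and in Magi1, a membrane scaffold protein, at 5.19 ± 0.815 against 0.0293 ± 0.0327 FPKM. Ccr6, a chemokine receptor, was at 54.1 ± 6.65 against 24.4 ± 2.29 FPKM, Cpm at 15.7 ± 2.44 against 5.92 ± 0.646 FPKM, Plekhg3 at 5.90 ± 1.21 against 2.03 ± 0.245 FPKM, and Pdcd4 at 74.1 ± 6.35 against 35.7 ± 1.49 FPKM, all lower with adjusted p at or under 2.85e-04. The transcription factor gene Ets1 fell from 185 ± 22.1 to 105 ± 1.38 FPKM, while Irf8 rose from 184 ± 32.5 to 311 ± 9.88 FPKM, and these were the 2 calls among 20 B lineage transcription factors. After upper quartile rescaling 12 of them were lower and 1 higher (camera adjusted p = 0.00529, or 0.219 with an estimated correlation). With the authors' scaling camera did not call this list (adjusted p = 0.0904, or 0.963 with an estimated correlation). Of 11 costimulation and checkpoint ligands 5 rose and 2 fell (camera adjusted p = 0.790, 5 higher and 3 lower adjusted over the list alone), the risers including Tnfsf4 at 0.234 ± 0.246 against 2.09 ± 0.336 FPKM and Cd80 at 0.930 ± 0.336 against 2.70 ± 0.523 FPKM. Pdcd1, an inhibitory receptor, was at 0.09997 ± 0.173 against 3.65 ± 0.4996 FPKM, and the early response gene Jun at 12.3 ± 2.35 against 52.5 ± 2.87 FPKM. In the Toll-like receptor pathway 4 of 18 genes rose, with Tlr7 at 12.03 ± 1.5001 against 22.9 ± 1.33 FPKM, and 3 fell, with Ly86 at 104 ± 12.5 against 53.4 ± 2.29 FPKM (camera adjusted p = 0.177, 5 higher and 3 lower adjusted over the list alone). Uhrf1, which guides maintenance methylation of DNA, was at 8.70 ± 2.36 against 26.0 ± 0.851 FPKM, and it was among 3 of 21 DNA methylation and corepressor genes that rose (2 higher and 0 lower adjusted over the list alone), where 7 others were lower after upper quartile rescaling. Genes higher and lower after that rescaling numbered 5 and 5 among costimulation and checkpoint ligands (camera adjusted p = 0.656) and 5 and 8 in the Toll-like receptor pathway (camera adjusted p = 0.332).

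Markers of other cell types were also tested in CD93-negative cells. Of 12 tested T cell markers 7 rose (median log2 change 0.55 relative to all tested genes, camera adjusted p = 0.0451, or 0.916 with an estimated correlation, 8 higher and 0 lower adjusted over the list alone), for example Cd3g at 1.65 ± 0.906 against 4.52 ± 1.12 FPKM and Cd8a at 1.98 ± 0.564 against 4.87 ± 0.543 FPKM. Of 7 tested red cell markers 5 rose (median log2 change 1.54 relative to all tested genes, camera adjusted p = 0.0162, or 0.484 with an estimated correlation, 5 higher and 0 lower adjusted over the list alone), for example Slc4a1 at 0.630 ± 0.264 against 4.12 ± 0.568 FPKM and the globin gene Hba-a1 at 27.1, 32.5 and 0.00930 FPKM in control and 72.3, 62.8 and 103 FPKM in DKO-labelled libraries. Without control replicate 3 the log2 change of Hba-a1 went from 3.001 to 1.36. Hba-a1 lost its call without control replicate 1 (log2 change 3.76, adjusted p = 0.0775, with 1.39e-81 to 0.239 over its alternatives, the lowest with the replicate number as a block). That lowest value does not reflect the spread of its own control values. Reads of the globin genes could be split between near-identical copies. The macrophage gene C1qb was at 0.7498 ± 0.379 against 4.22 ± 0.636 FPKM, and 2 of 6 tested macrophage markers rose (camera adjusted p = 0.983, 2 higher and 1 lower adjusted over the list alone). No neutrophil marker among 5 tested passed the adjusted p of limma and 1 an unadjusted p under 0.05, with 2 lower after upper quartile rescaling, and NK cell markers had 1 of 10 called, Gzmb. In all 6 CD93-negative libraries the Y-linked gene Ddx3y was at 23.0 to 30.7 FPKM and Xist, expressed from the inactive X chromosome of females, at 0.0986 to 0.250 FPKM, as in male mice. Genes higher and lower after upper quartile rescaling numbered 6 and 1 among T cell markers, 3 and 0 among red cell markers and 2 and 1 among macrophage markers. Of 32 lists tested, camera called 14, and the other 18 had adjusted p from 0.0539 to 0.983. With an estimated correlation it called 0 with the authors' scaling, 3 at an unadjusted p under 0.05, and after upper quartile rescaling 1, the interferon-stimulated genes (adjusted p = 0.0320). Of 111 named genes, 6 lost their call after upper quartile rescaling, 2 gained one, and 0 changed direction.

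**Figure D1:**
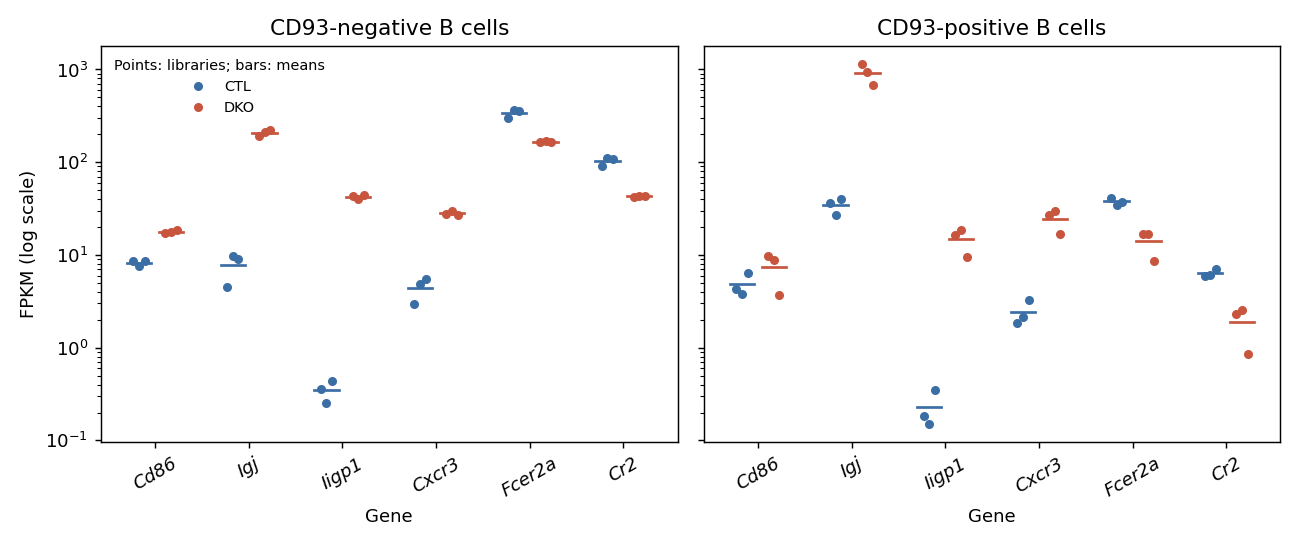
FPKM of 6 named genes in each library (points, log axis) with group means (bars), control in blue and DKO-labelled in red, in CD93-negative and CD93-positive B cells. Igj, Iigp1 and Cxcr3 lie higher and Fcer2a and Cr2 lower in DKO-labelled libraries of both sorts, while the Cd86 difference in CD93-positive cells had an adjusted p of 0.606 with the authors' scaling and 0.0342 after upper quartile rescaling.

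The second comparison asked the same of CD93-positive B cells. Igj rose from 34.7 ± 7.01 to 923 ± 230.2 FPKM, a 26.6-fold difference of the means (log2 change 4.68, SE 0.43, adjusted p = 4.86e-25). That p-value rests on a spread shared over genes rather than on the replicates of Igj alone. Ly6a, a surface antigen of activated lymphocytes, rose from 22.4 ± 9.69 to 299.6 ± 91.8 FPKM, Iigp1 from 0.227 ± 0.106 to 14.8 ± 4.64 FPKM, and Cxcr3 from 2.42 ± 0.745 to 24.5 ± 6.95 FPKM. Cr2 fell from 6.32 ± 0.667 to 1.90 ± 0.915 FPKM. Cd86 was at 4.85 ± 1.39 against 7.42 ± 3.24 FPKM, with a log2 change of 0.46 (SE 0.33, adjusted p = 0.606) with the authors' scaling. After upper quartile rescaling the change was 0.66 and passed (adjusted p = 0.0342), as did 0.79 without DKO replicate 3 (adjusted p = 0.0323). With sex as a covariate after rescaling it was 0.38 (adjusted p = 0.277). Cd86 passed under 4 of 21 alternative settings, with adjusted p from 0.0323 to 0.998.

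Of 11250 genes tested, 361 passed an adjusted p of 0.05, 188 higher and 173 lower, with a median log2 change of -0.22 over all tested genes. Small RNA genes made up 48 of these calls, 35 of them lower. DKO replicate 3 lay apart from the other libraries. Its tested genes had an upper quartile of 15.4 FPKM, against 25.8 to 30.05 FPKM in the other libraries. After upper quartile rescaling 2331 genes were called, 1280 higher and 1051 lower, with a median of -0.01, and 227 of the 361 were among them in the same direction. Without DKO replicate 3, 539 genes were higher and 136 lower with the authors' scaling, and 954 and 674 after rescaling. Scaling to a common sum without globins gave 788 higher and 2409 lower, so the direction of the split depended on scaling. Leaving out control replicate 1 gave 163 calls and leaving out control replicate 2 gave 189. Sex differed between the groups. Xist was at 0.594 and 0.429 FPKM in control replicates 1 and 2, at 59.4 FPKM in control replicate 3, and between 19.7 and 50.7 FPKM in the DKO-labelled libraries, so that only 1 control library was female-like. A sex covariate therefore compares the DKO-labelled libraries with control replicate 3 alone. Control replicates 1 and 2 also held the most globin, so the covariate cannot separate sex from red cell content. With sex as a covariate and upper quartile rescaling 570 genes were called, 398 higher and 172 lower.

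**Figure D2:**
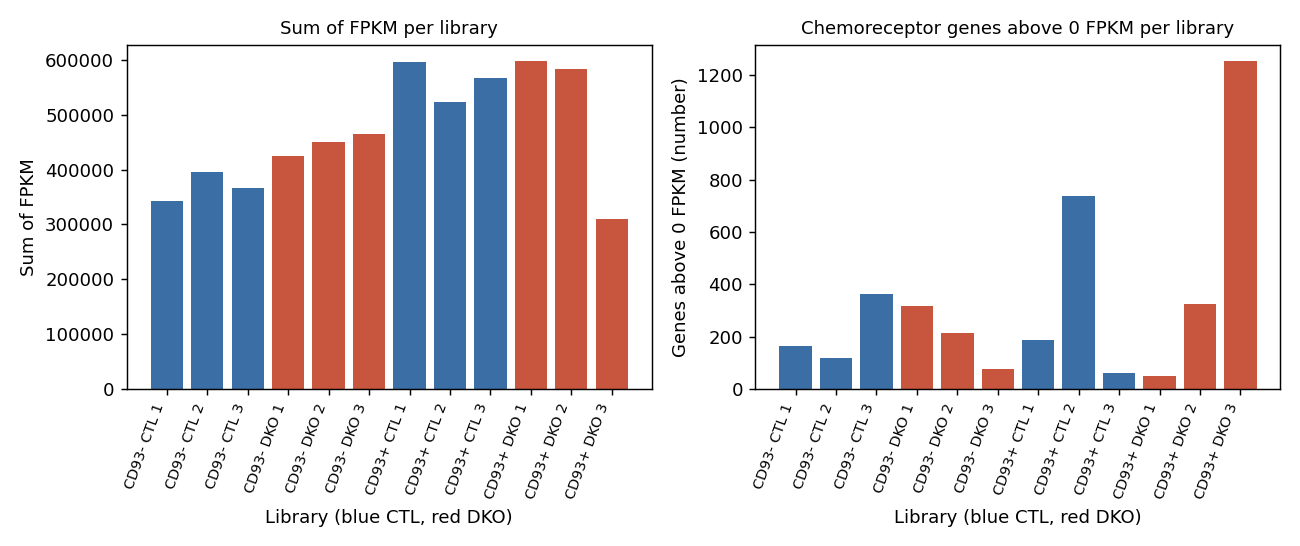
Sum of FPKM (left) and number of chemoreceptor genes with a value above 0 (right) in each library, control in blue and DKO-labelled in red. CD93-positive DKO replicate 3 has the lowest sum, 309359 FPKM, and the most chemoreceptor genes above 0, 1254 of 1373.

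Among 17 tested plasma cell genes, those higher numbered 9 with the authors' scaling, 13 after upper quartile rescaling and 13 after rescaling without DKO replicate 3 (and 0, 1 and 0 lower), and 12 passed with the authors' scaling adjusted over the list alone (median log2 change 1.55 relative to all tested genes, camera adjusted p = 1.15e-31, or 0.494 with an estimated correlation). Fkbp11, a peptidyl-prolyl isomerase of the secretory pathway, was at 1.45 ± 0.639 against 16.8 ± 5.62 FPKM, and Derl3, of endoplasmic reticulum protein degradation, at 6.23 ± 2.59 against 44.1 ± 15.8 FPKM. Under the same 3 settings 3, 12 and 12 of 15 genes of the unfolded protein response were higher, and 8 adjusted over the list alone (median log2 change 1.21 relative to all tested genes, camera adjusted p = 1.05e-12, or 0.494 with an estimated correlation). Xbp1 was at 40.9 ± 9.40 against 158 ± 49.4 FPKM (log2 change 1.90, adjusted p = 2.68e-04), and lost its call without control replicate 1 (adjusted p = 0.0526) or 2 (adjusted p = 0.0565), with 1.76e-04 to 0.689 over its alternatives. Without these libraries its log2 change was 1.86 and 1.76. Zbp1 was at 13.1 ± 3.80 against 52.2 ± 21.3 FPKM. Of 25 interferon-stimulated genes 3, 5 and 5 (and 1, 0 and 0 lower) were higher, and 3 adjusted over the list alone (median log2 change 0.38 relative to all tested genes, camera adjusted p = 4.43e-04, or 0.851 with an estimated correlation). In the same list 1 gene was lower with the authors' scaling, Rsad2, at 102, 102 and 25.5 FPKM in control and 25.9, 25.4 and 6.01 FPKM in DKO-labelled libraries. It lost its call without control replicate 1 (adjusted p = 0.0949), control replicate 2 (adjusted p = 0.0651) or DKO replicate 3 (adjusted p = 0.178), with 3.60e-05 to 0.948 over its alternatives. Its log2 change of -1.94 became -1.61, -1.62 and -1.30 without these libraries. Control replicate 3 was at the level of DKO replicates 1 and 2, while control replicates 1 and 2 were male-like and globin-rich. Of 25 proliferation genes 0, 8 and 2 were higher (camera adjusted p = 0.246, 0 higher and 0 lower adjusted over the list alone), and with the authors' scaling limma gave 1 higher and 0 lower at an unadjusted p under 0.05. With sex as a covariate after rescaling 12 plasma cell genes, 9 of the unfolded protein response, 4 interferon-stimulated and 3 proliferation genes were higher. The camera adjusted p after upper quartile rescaling was 7.06e-09 for plasma cell genes, 2.53e-09 for the unfolded protein response and 0.00105 for interferon-stimulated genes, and with an estimated correlation 0.210 for each. For proliferation genes it was 0.00123, 0.00956 without DKO replicate 3 and 5.75e-05 with sex as a covariate after rescaling. These 3 values with an estimated correlation were 0.558, 0.554 and 0.410. The list had a median of 0.20 relative to all tested genes after rescaling. Of 10 heat shock genes 0, 8 and 5 were higher under the 3 settings (median log2 change 0.56 relative to all tested genes, camera adjusted p = 0.0111, or 0.851 with an estimated correlation, 0 higher and 0 lower adjusted over the list alone), with a camera adjusted p of 1.48e-04 after rescaling, or 0.210 with an estimated correlation. With the authors' scaling limma called 0 of them and 1 were higher at an unadjusted p under 0.05. Of 15 glycolysis genes 0, 10 and 8 were higher (median log2 change 0.35 relative to all tested genes, camera adjusted p = 0.0517, or 0.962 with an estimated correlation, 0 higher and 0 lower adjusted over the list alone), with a camera adjusted p of 3.27e-05 after rescaling, or 0.210 with an estimated correlation, and 0 higher in limma at an unadjusted p with the authors' scaling.

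Lists of B cell subsets again held risers. Of 14 genes of age-associated B cells 5, 10 and 9 (and 0, 2 and 2 lower) were higher under these 3 settings, and 7 adjusted over the list alone (median log2 change 0.92 relative to all tested genes, camera adjusted p = 1.44e-09, or 0.494 with an estimated correlation). Zbtb32, a transcriptional repressor, was at 1.25 ± 0.252 against 6.51 ± 2.80 FPKM, and Nt5e, the ectonucleotidase CD73, at 0.394 ± 0.151 against 2.65 ± 1.07 FPKM. In the B-1 cell list 3, 8 and 9 (and 1, 1 and 1 lower) of 14 genes were higher, and 4 adjusted over the list alone (median log2 change 0.69 relative to all tested genes, camera adjusted p = 2.43e-05, or 0.609 with an estimated correlation). In the germinal center list, whose median change was -0.03 and mean change 0.21, 3, 4 and 4 of 13 were higher (median log2 change 0.19 relative to all tested genes, camera adjusted p = 0.0111, or 0.851 with an estimated correlation, 4 higher and 0 lower adjusted over the list alone), with Gm600 at 0.272 ± 0.110 against 2.57 ± 0.895 FPKM. Of 14 cytokine and chemokine genes 6, 7 and 7 (and 0, 1 and 1 lower) were higher, and 7 adjusted over the list alone (median log2 change 0.81 relative to all tested genes, camera adjusted p = 2.38e-08, or 0.494 with an estimated correlation), with Ccl3 at 0.221 ± 0.205 against 5.51 ± 2.57 FPKM and Ccl4 at 0.438 ± 0.306 against 7.001 ± 2.71 FPKM. Cdkn2a, a cell cycle inhibitor locus, was at 0.502 ± 0.310 against 14.4 ± 7.22 FPKM, Chst1, a sulfotransferase, at 0.298 ± 0.152 against 7.71 ± 2.55 FPKM. The inhibitory receptors Lag3, Pdcd1 and Ctla4 were at 1.23 ± 0.349 against 14.98 ± 6.20 FPKM, 1.31 ± 0.557 against 6.56 ± 2.08 FPKM and 0.638 ± 0.199 against 3.44 ± 1.84 FPKM. Pdcd1 and Ctla4 belong to a list of inhibitory receptors and phosphatases in which 3, 4 and 5 (and 0, 6 and 5 lower) of 17 genes were higher (median log2 change -0.27 relative to all tested genes, camera adjusted p = 0.690, or 0.998 with an estimated correlation, 3 higher and 0 lower adjusted over the list alone). Its camera adjusted p after upper quartile rescaling was 0.198. NK cell markers were higher in 2, 4 and 5 of 9 genes (median log2 change 0.92 relative to all tested genes, camera adjusted p = 8.90e-07, or 0.494 with an estimated correlation, 5 higher and 0 lower adjusted over the list alone), with Gzmb at 0.608 ± 0.206 against 6.30 ± 4.76 FPKM. T cell markers were higher in 1, 2 and 6 of 14 (median log2 change 0.42 relative to all tested genes, camera adjusted p = 0.0202, or 0.962 with an estimated correlation, 1 higher and 0 lower adjusted over the list alone). With sex as a covariate after rescaling limma called 0 NK cell and 0 T cell markers, and 4 and 1 were higher at an unadjusted p under 0.05. Gzmb then had a log2 change of 1.94, against 1.91 with the authors' scaling, and an adjusted p of 0.128, with 1.33e-10 to 0.511 over its alternatives. Under that setting 4 age-associated, 4 B-1, 3 germinal center and 3 cytokine genes were higher. Without that covariate the camera adjusted p after upper quartile rescaling was 1.48e-04 for age-associated, 3.79e-04 for B-1 and 0.00466 for cytokine genes. It was 0.00105 for NK cell and 0.0442 for T cell markers. The germinal center list was no longer called (adjusted p = 0.129), though its median relative to all tested genes was still 0.19. Over these 6 lists the adjusted p with an estimated correlation was 0.210 to 0.620.

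Fewer B lineage genes passed the test with the authors' scaling than after rescaling. Fcer2a was at 37.8 ± 2.96 against 14.1 ± 4.86 FPKM (log2 change -1.41, adjusted p = 0.00808). Without control replicates 1 to 3 in turn the change was -1.36, -1.47 and -1.41, and the call was lost (adjusted p = 0.298, 0.126 and 0.110). Over its alternatives the change was -1.56 to -1.08 and the adjusted p 4.79e-04 to 0.715. After upper quartile rescaling it was -1.18 and passed (adjusted p = 5.17e-04), as it did without DKO replicate 3 (adjusted p = 0.00286) and with sex as a covariate (adjusted p = 0.00696). Tmem132e was at 16.7 ± 0.920 against 3.69 ± 1.07 FPKM. Among 20 B lineage transcription factors 0 with the authors' scaling, 15 after upper quartile rescaling and 12 after rescaling without DKO replicate 3 were lower (median log2 change -0.49 relative to all tested genes, camera adjusted p = 1.37e-04, or 0.851 with an estimated correlation, 0 higher and 0 lower adjusted over the list alone), and 5 were lower in limma at an unadjusted p under 0.05 with the authors' scaling. Of 19 B cell receptor signalling genes 1, 10 and 6 were lower (median log2 change -0.29 relative to all tested genes, camera adjusted p = 0.00672, or 0.962 with an estimated correlation, 0 higher and 1 lower adjusted over the list alone). Of 10 pan-B cell markers 2, 7 and 6 were lower (median log2 change -0.46 relative to all tested genes, camera adjusted p = 4.43e-04, or 0.851 with an estimated correlation, 0 higher and 2 lower adjusted over the list alone). Marginal zone genes had 1, 5 and 4 (and 1, 2 and 2 higher) of 15 lower (camera adjusted p = 0.0756, or 0.962 with an estimated correlation, 1 higher and 5 lower adjusted over the list alone). With sex as a covariate after rescaling 7 transcription factors, 1 receptor signalling gene, 4 pan-B cell markers and 3 marginal zone genes were lower. Without that covariate the camera adjusted p after upper quartile rescaling was 3.39e-08, 5.29e-05, 7.96e-06 and 0.0477 for these lists in turn. With an estimated correlation it was 0.210, 0.315, 0.210 and 0.469, so that none was called. Of 12 transitional B cell genes 0, 2 and 3 were lower under the same 3 settings. Their median log2 change with the authors' scaling was -0.28 relative to all tested genes (camera adjusted p = 0.0561, or 0.962 with an estimated correlation). After upper quartile rescaling the camera adjusted p was 0.00571, and 0.00518 without DKO replicate 3, or 0.469 and 0.453 with an estimated correlation. With sex as a covariate after rescaling the relative median was -0.44. Cd93 itself was at 53.9 ± 5.22 against 40.5 ± 11.5 FPKM (adjusted p = 0.704).

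Red cell and neutrophil transcripts were lower in DKO-labelled CD93-positive libraries with the authors' scaling, but not under every setting. Control replicates 1 and 2 were both male-like and globin-rich, so a sex covariate cannot separate sex from red cell content. With sex as a covariate after upper quartile rescaling the red cell markers had a median log2 change of 0.08 against control replicate 3 alone. Neutrophil markers then had 0 lower in limma, and 5 at an unadjusted p under 0.05, with a camera adjusted p of 0.0184, or 0.363 with an estimated correlation. Of 11 red cell markers 6, 0 and 0 were lower with the authors' scaling, after upper quartile rescaling and after rescaling without DKO replicate 3 (median log2 change -1.57 relative to all tested genes, camera adjusted p = 5.10e-12, or 0.494 with an estimated correlation, 0 higher and 7 lower adjusted over the list alone). After rescaling that median was -1.54, and -1.14 without DKO replicate 3, so the calls were lost while most of the decrease remained. Of 11 neutrophil markers 3, 6 and 5 were lower (median log2 change -0.86 relative to all tested genes, camera adjusted p = 2.51e-04, or 0.494 with an estimated correlation, 0 higher and 7 lower adjusted over the list alone). The camera adjusted p after upper quartile rescaling was 0.0882 for red cell and 0.00675 for neutrophil markers, or 0.726 and 0.315 with an estimated correlation. Globin genes held 16.3% and 15.8% of the FPKM sum in control replicates 1 and 2, 4.21% in control replicate 3, and 1.60% to 4.09% in the DKO-labelled libraries. Control replicate 3 was thus at the level of the DKO-labelled libraries. Alas2, of haem synthesis in red cells, was at 456, 424 and 104 FPKM in control and 74.9, 82.5 and 18.7 FPKM in DKO-labelled libraries. Among the named decreases, Tmcc2, Alas2, Hbb-b2, Ypel4, Beta-s, Ube2o and Slc25a37 followed this pattern in having their highest values in control replicates 1 and 2, and all 7 lost their call without DKO replicate 3 (adjusted p from 0.0809 to 0.175). Hbb-b2, Beta-s, Ube2o and Slc25a37 also lost it without control replicate 1 (adjusted p from 0.144 to 0.301), and the last 3 of these without control replicate 2 (adjusted p from 0.0550 to 0.191). Over their alternatives the adjusted p of the 7 genes ran from 1.86e-08 to 0.948. Their log2 changes were -2.57 to -1.69 with all libraries, -1.86 to -1.20 without DKO replicate 3, and -0.74 to -0.43 with sex as a covariate after rescaling. These 7 genes were picked as decreases. In that last fit the 11 red cell markers as a whole had a median of 0.08 and a mean of 0.18. Of 32 lists tested, camera called 15, and the other 17 had adjusted p from 0.0517 to 0.995. With an estimated correlation it called 0, and 1 at an unadjusted p under 0.05, and fry called 0, and 1 at an unadjusted p, with the authors' scaling, against 19 after upper quartile rescaling. Camera with an estimated correlation called 0 after that rescaling, and 6 at an unadjusted p.

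The third comparison asked whether the 2 sorts of B cells changed alike. The tables were scaled separately, so the sizes of their changes were not tested against each other. Among 10446 genes tested in both, 110 were called higher in both sorts, against 27.2 for independent lists of 1973 and 144 genes, and 21 were called lower in both, against 2.56. Opposite calls numbered 14, against 23.0. After upper quartile rescaling 766 genes were higher in both, against 208, 684 were lower in both, against 241, and 43 went opposite ways, against 462. Without CD93-positive DKO replicate 3 these were 585, 438 and 39. Across genes, which are not independent replicates, the log2 changes had Pearson's r = 0.391 and Spearman's rho = 0.480 with the authors' scaling. Igj, Iigp1, Tgtp1, Cxcr3, Zbtb32, Nt5e, Pdcd1 and Zbp1 were among the genes higher in both sorts, and Cr2 and Fcer2a among those lower in both.

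**Figure D3:**
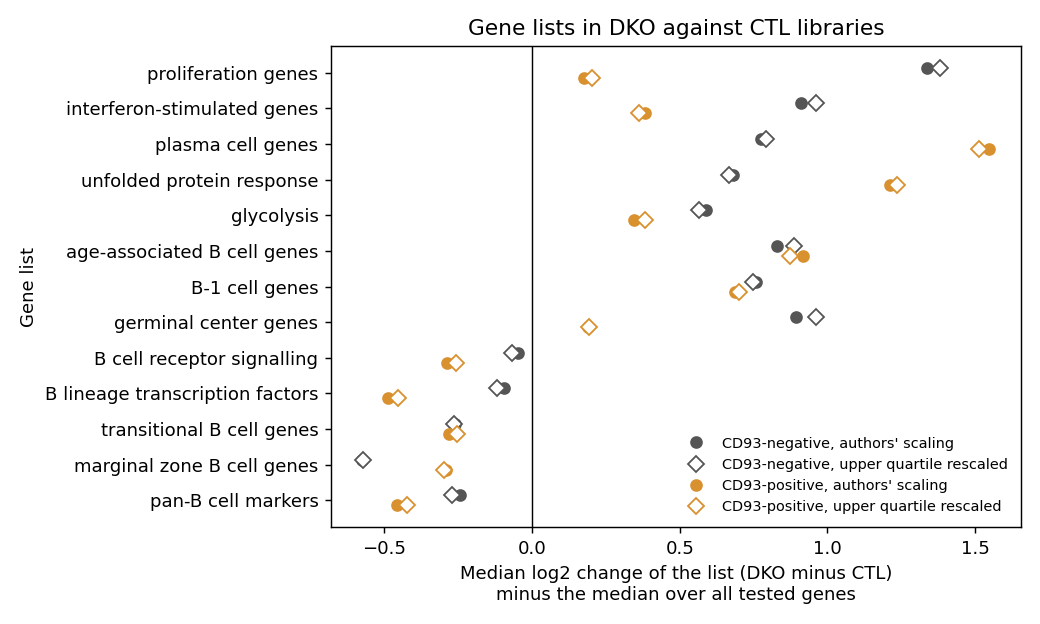
Median log2 change of 13 gene lists, DKO minus control, less the median over all tested genes, in CD93-negative (grey) and CD93-positive (orange) B cells. Filled circles use the authors' scaling and open diamonds upper quartile rescaling. Plasma cell genes lie at 0.78 and 1.55 with the authors' scaling, proliferation genes at 1.34 and 0.18.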

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

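The genes below were singled out because every library of 1 sort moved one way and every library of the other sort the opposite way, and the difference itself was not tested because the tables were scaled separately. Alas2, Beta-s and Hbb-b2 are genes of red cells. Alas2 had a log2 change of 0.80 in CD93-negative and -2.45 in CD93-positive libraries. Beta-s, a beta globin gene, had 1.75 and -2.13. Hbb-b2 had 3.004 and -2.17. In CD93-negative cells Hbb-b2 was at 0.00127, 15.8 and 19.9 FPKM in control libraries, and without control replicate 1 its log2 change was 1.59 (adjusted p = 0.00557). It lost its call after upper quartile rescaling (log2 change 2.90, adjusted p = 0.0716, with 7.71e-80 to 0.172 over its alternatives). The lowest of these does not reflect the spread of its own control values. Without DKO replicate 3 the CD93-positive changes of Hbb-b2 and Beta-s were -1.41 and -1.40, and neither was called (adjusted p = 0.159 and 0.175). Tmcc2 had 0.94 and -2.57. Sex differed between the CD93-positive groups, and control replicates 1 and 2 were both male-like and globin-rich. Sex and red cell content therefore cannot be told apart. The CD93-positive log2 changes of Tmcc2, Alas2, Hbb-b2 and Beta-s with sex as a covariate after upper quartile rescaling were -0.72, -0.74, -0.63 and -0.59. They are changes against control replicate 3 alone, in a fit where the 11 red cell markers had a median log2 change of 0.08. After rescaling without that covariate they were -2.34, -2.21, -1.92 and -1.89, with adjusted p from 0.0541 to 0.0731. Globins took 0.0181% to 0.0636% of the FPKM sum in CD93-negative and 1.60% to 16.3% in CD93-positive libraries. With groups of 3 libraries, no test for a single library apart from its group was run.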

How the results depend on the processing

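The sex covariate, rescaling without DKO replicate 3, background subtraction, globin exclusion, removal of small RNA genes and the rescaled agreement counts were chosen after the data were seen. The cause of each shift below was not tested, except that the stricter and absent filters change which genes are tested. In CD93-negative cells the 2351 calls became 4478 after upper quartile rescaling and 4198 with quantile normalization, and leaving out 1 library gave 1430 to 3253. The other settings stayed within 1.5 times. In CD93-positive cells the 361 calls became 2331 after upper quartile rescaling, 2230 with quantile normalization, 16 with no filter, 168 with the stricter filter, 188 without the trend and 783 with sample quality weights. Those weights did not settle, with 3.24e-06 for DKO replicate 2. Added settings gave 127 with the sex covariate, 570 with it after rescaling, 1628 after rescaling without DKO replicate 3, 2022 after background subtraction and rescaling, and 3197 with globins excluded. With globins excluded 788 genes were higher and 2409 lower. Leaving out 1 library gave 163 to 675.

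Same-numbered libraries did not deviate together, with correlations of residuals in the CD93-negative table of 0.0237, -0.113 and -0.0858, and in the CD93-positive table of 0.166, -0.113 and -0.139. The replicate block gave 2874 calls in CD93-negative and 237 in CD93-positive cells, 10 and 15 lists, and 101 shared calls. With the block, calls in opposite directions numbered 28 against 15.8 for independent lists, where the fit without it had 14 against 23.0. Most of the 28 were small RNA genes or genes of red cells. Small RNA calls in CD93-negative cells went from 17 to 76 with the block. Genes are not independent, and the excess was not tested.

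Of the lists, 14 passed in CD93-negative cells and 15 in CD93-positive cells. With an estimated correlation 0 and 0 passed (3 and 1 at an unadjusted p), and with fry 13 and 0. Leaving out 1 library gave 13 to 15 and 15 to 17 lists. Shared calls went from 131 to 85 at an adjusted p of 0.01, 1450 after rescaling and 1023 after rescaling without DKO replicate 3. Among named genes in CD93-positive cells, Xist turned to -1.04 with the sex covariate and -0.70 with it after rescaling, and Oasl2 to -0.18 with the sex covariate. Tet2, not called under any setting tried, went from -0.29 to 0.08 with sample quality weights and 0.01 with the sex covariate after rescaling. Of 67 named genes tested there, 13 lost their call after rescaling and 57 with no filter. Alternatives meant for counts did not apply. Planned results on the 12 samples not analysed here were not run. Depth is unknown, so how it limits low genes cannot be given.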

Other observations

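Of the tests in this part, those of the interferon-inducible GTPases and of the T cell genes were chosen after the values had been seen, and those of the proteasome, the respiratory chain, the silent genes and the splits before. The MHC class I, ribosomal protein and zinc finger families were tested without a bound written beforehand. Gene families taken by their names, and not on the fixed lists as such, also moved. Of 17 interferon-inducible GTPases 16 rose in CD93-negative cells, with a median log2 change of 1.74, and in CD93-positive cells 10 of 16, with a median of 1.60. The larger camera adjusted p of the 2 sorts was 4.67e-20, and with an estimated correlation the adjusted p was 0.154 and 0.0981, or 0.01003 and 0.0890 after upper quartile rescaling. This family was picked for its rise, so its test does not bear on whether such families rise. Reads of these GTPases could be split between near-identical copies. MHC class I genes rose in 17 of 19 tested members in CD93-negative cells, and in 2 of 18 in CD93-positive cells, or 16 after upper quartile rescaling. With an estimated correlation the adjusted p of this family was 0.264 and 0.329, or 0.01003 and 0.0890 after rescaling. Ribosomal protein genes rose in 69 of 78 tested members in CD93-negative cells. In CD93-positive cells 0 of 79 rose in limma with the authors' scaling, 1 at an unadjusted p under 0.05, and 44 rose after rescaling. With an estimated correlation their adjusted p was 0.322 and 0.693, or 0.1998 and 0.190 after rescaling. Zinc finger genes went the other way, with 9 of 267 lower and 3 higher in CD93-negative cells, or 110 and 2 after rescaling. In CD93-positive cells 0 of 251 were lower in limma, 24 at an unadjusted p, and 27 after rescaling. Their camera adjusted p was 1.11e-09 and 0.0151, and with an estimated correlation 0.322 and 0.693, or 0.01003 and 0.164 after rescaling.

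A hypothesis that proteasome genes were higher in both sorts was tested the same way. In CD93-negative cells 32 of 46 rose, with a median of 0.52, and in CD93-positive cells 0 of 46 with the authors' scaling (1 higher and 1 lower in limma at an unadjusted p under 0.05) and 27 after upper quartile rescaling. The larger camera adjusted p was 7.35e-04, and with an estimated correlation the adjusted p was 0.322 and 0.693, or 0.0567 and 0.164 after rescaling. For genes of the mitochondrial respiratory chain 58 of 73 rose in CD93-negative cells, and in CD93-positive cells 0 of 73 with the authors' scaling (0 higher and 2 lower at an unadjusted p, 1 lower when adjusted) and 41 after rescaling. The larger camera adjusted p was 4.64e-04, and 0.322 and 0.693 with an estimated correlation, or 0.0969 and 0.167 after rescaling. Their gain is relative to other genes, since the CD93-positive median was 0.10 where all tested genes had -0.22.

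CD93-positive DKO replicate 3 had 1254 of 1373 chemoreceptor genes above 0, where the other 5 libraries had 50 to 739. In a second set of 221 genes silent in B cells (vomeronasal type 2, beta-defensin and keratin-associated genes) a share of 0.846 was above 0 in that library. Greater depth alone is argued against, since the mean FPKM of that set was 6.09 times the median of the other libraries and depth alone would leave a mean FPKM where it was. Activation of silent genes by the deficiency is argued against, since the highest control library had 4.34 times the mean of the lowest DKO-labelled library. Fragments of genomic DNA remain a candidate explanation. The mean was 0.277 FPKM in the second set and 0.796 FPKM in chemoreceptors. Chemoreceptors were also the higher set in the other CD93-positive libraries, with 0.0752 and 0.237 FPKM in control replicate 2. The difference between the sets therefore does not bear on that explanation.

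Lag3, Tigit, Ctla4, Pdcd1 and Folr4, receptors of T and other activated lymphocytes, had a median log2 change of 2.54 in CD93-positive cells after upper quartile rescaling. They were picked for their rise, so the size of that change excludes nothing. The 14 markers of the fixed T cell list had a median of 0.40 (SD 0.48), and without DKO replicate 3 0.53 (SD 0.48), with 6 of them called higher. The bound for a larger share of T cells of the kind present in controls was a median above the SD of the markers. The median of 0.40 did not reach it, and 0.53 without DKO replicate 3 did. That SD is a spread between genes and not the error of the median, so this explanation remains open. Receptor transcripts made by the B cells themselves and T cells of an activated kind also remain open. The 4 receptors tested in CD93-negative cells had a median change of 1.30 after rescaling, and the fixed T cell list, with 12 tested members there, 0.50. A separate set of T cell genes had 0.49 (SD 0.47) over 7 tested members in CD93-negative cells. In CD93-positive cells that set had 0.12 (SD 0.40) over 9. The sources named above cannot be told apart in bulk values.

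The 6 libraries of each sort form 10 splits into groups of 3, too few for a share under 0.05. In CD93-negative cells the real split gave 2351 calls and the highest other 4, and 1 of the 10 splits, the real one, gave as many. In CD93-positive cells the real split gave 361 and the highest other 150, and 1 split gave as many.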
